A study of Seriola lalandi dorsalis with 18 samples.

How the data were processed

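Poly(A) RNA libraries were made from whole larvae of the California yellowtail, a marine fish reared for aquaculture, that had been measured under a microscope and sorted by body size before preservation. The 18 libraries fall into 6 groups of 3 replicates: large and small larvae at 2, 7 and 17 days post hatching (dph). Per the series' design text, the replicates of an age are separate spawning events. The labels do not say how many larvae were pooled in a library.

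The values the authors deposited are expected counts per gene and per isoform, the kind of estimate RSEM makes from aligned reads, not scaled for depth or length. The submitters' processing notes name RSEM (no version stated), Bowtie2 2.2.0, which is an aligner, and DESeq2 1.2.10, without saying how each was run. The assembly that defined the genes, its filters and its annotation are not given in the sources used here. There were 222498 genes and 244022 isoforms, and every gene equals the sum of its isoforms within 0.05 reads. Of 4004964 gene values, 13 were not whole (tolerance 0). The expected counts were rounded to whole numbers first. Of all genes, 370 had no read in any library. Because RSEM divides reads among similar sequences, values of near-identical copies are uncertain, and a gene of a transcript assembly can be a fragment of a longer gene. Since nearly all deposited values are whole, they do not show whether or how such reads were divided.

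Gene identifiers are component numbers of an assembly. The table of yellowtail gene names of the RefSeq assembly Sedor1 matched 0 of them, so no gene has a name here, and the lists of digestive, yolk, muscle, growth, lens, blood and other tissue genes fixed before the data were examined could not be applied. No sequence was used here, so position, annotation, length and GC content were not analysed. At most 2 rising and 2 falling identifiers are named per comparison. They were chosen by a rule fixed before the data were examined: among genes at an adjusted p below 0.05, with a mean of at least 10 CPM in the libraries compared, and with the same direction in all pairs (size) or no overlap between the ages (age), those with the largest rise and fall in log2 fold change.

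Depth ranged from 3706225 reads in 2 dph large replicate 2 to 34341948 in 17 dph large replicate 1, with 243726780 reads in all. Between 97.73% and 98.862% of a library's reads lay in tested genes. No pair of libraries of a group was a duplicate: chi-square per degree of freedom between them ran from 2.956 to 33.55. Intervals and limits from counts cover counting error only. A gene with 0 reads in a group is given the limit of 3 reads over that group's libraries.

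Size was tested with edgeR 4.0.16 in R 4.3.3 by quasi-likelihood tests (glmQLFit and glmQLFTest with a trended dispersion) over all 18 libraries, with 6 group means, TMM scaling and filterByExpr, which kept 68642 genes. Contrasts were large against small at each age, their mean over the 3 ages, and differences of the size effect between ages. Age was tested in the same way on counts summed over the large and small library of each spawn (9 sums, 80333 genes), since these libraries share a spawn. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The SE given for a log2 change is its absolute value divided by the square root of the quasi-likelihood F statistic. It is thus worked back from the test and not estimated directly. CPM values are scaled by TMM, and log2 CPM uses a prior count of 2. In counts simulated from the real means and depths, the size test at 17 dph (68642 genes) recovered 12% of genes changed 2-fold and 86% of genes changed 4-fold, with 4 false among 102 calls. The age test from 2 to 7 dph (80333 genes) recovered 20% and 96%, with 5 false among 121 calls. These simulations gave each gene the trended dispersion, without a spread of its own or any likeness of siblings. The real data may therefore do worse.

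Large and small libraries with the same age and replicate number carry the same collection code in the labels, so the number marks a shared spawn and pairs them. The residuals of the libraries of a pair from their group means correlated at 0.0878 (17 dph replicate 3) to 0.502. Among the small libraries of its age, each large library correlated best with that of its own number in 9 of 9 pairs. The small libraries were not compared in the other direction. The fit with each pair as a block was fixed as an alternative before the data were examined, and its values stand beside the results where they differ. Across ages the labels do not state what a number shares. Replicate 2 at 7 dph and replicate 2 at 17 dph carry the same code. Read as a month and day of collection, the codes give these 2 different hatch days, and a common hatch day to replicate 1 of all ages and to replicate 2 at 2 dph with replicate 3 at 7 and 17 dph. That is a reading of the codes, which the labels do not state.

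Library similarity is the Euclidean distance of log2 CPM over the 500 most variable tested genes, tested by exact permutation of the pairing within ages. Library composition is the share of reads in the 100 most abundant genes and the number of genes detected after thinning to 3706225 reads. The developmental index of a pair is the slope, over genes called between the ages the pair does not belong to, of its large minus small log2 CPM on the log2 change between those ages. These were tested by exact two-sided sign-flip permutation over the 9 pairs. Alternatives were other scalings, low-count filters, DESeq2 1.42.0 (on genes with at least 10 reads), tests against a fold change, libraries of a single age, isoforms, either size class alone, blocks, and each library, pair or spawn left out. After the data were examined, a set of genes nearly absent at 2 dph was defined (at most 5 reads over the 6 libraries at 2 dph and at least 100 reads over all libraries), and fits without it, with library totals as the only scaling, and with libraries thinned to the shallowest were added.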

Results

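Gene expression was measured by poly(A) RNA sequencing in California yellowtail larvae that had been sorted into large and small individuals at 2, 7 and 17 days post hatching (dph), to compare slow-growing and fast-growing larvae over successive growth stages. Each of the 6 groups held 3 libraries, and each large library had a small library from the same spawn. Depth was 3706225 to 34341948 reads per library. Genes are named by their assembly identifiers, which could not be paired with gene names.

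Averaged over all pairs of ages, age separated the libraries most. Over the 500 most variable genes, libraries of different ages lay 98.75 apart on average, a mean that was not split by pair of ages. Large and small larvae of different spawns of an age lay 37.12 apart, and those of the same spawn 26.46. At 2, 7 and 17 dph these were 25.28, 27.92 and 58.17 for different spawns and 11.5, 17.49 and 50.38 for the same spawn. Large and small siblings were thus closer to each other than to non-siblings of their age, with a distance ratio of 0.7128 (exact permutation of the pairing, one-sided p = 0.00463, the smallest that 216 pairings allow). The first principal component held 88.1% of the variance and 395 of the 500 genes were nearly absent at 2 dph (at most 5 reads over the 6 libraries of that age and at least 100 reads over all libraries). The 17 dph small library of replicate 3 lay at -17.96 on it, and the other 17 dph libraries lay between 22.46 and 73.87. The 2 dph libraries lay at -82.93 to -77.25. The 7 dph libraries lay at 28.18 to 47.66, within the 17 dph span, so this component did not part 7 from 17 dph. Without the nearly absent genes, the first component held 71.4%, the 17 dph small libraries lay at 29.88 to 33.28 and the 17 dph large libraries at 48.13 to 52.82. The 7 dph libraries then lay below all of these, at 8.198 to 20.02.

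**Figure D1:**
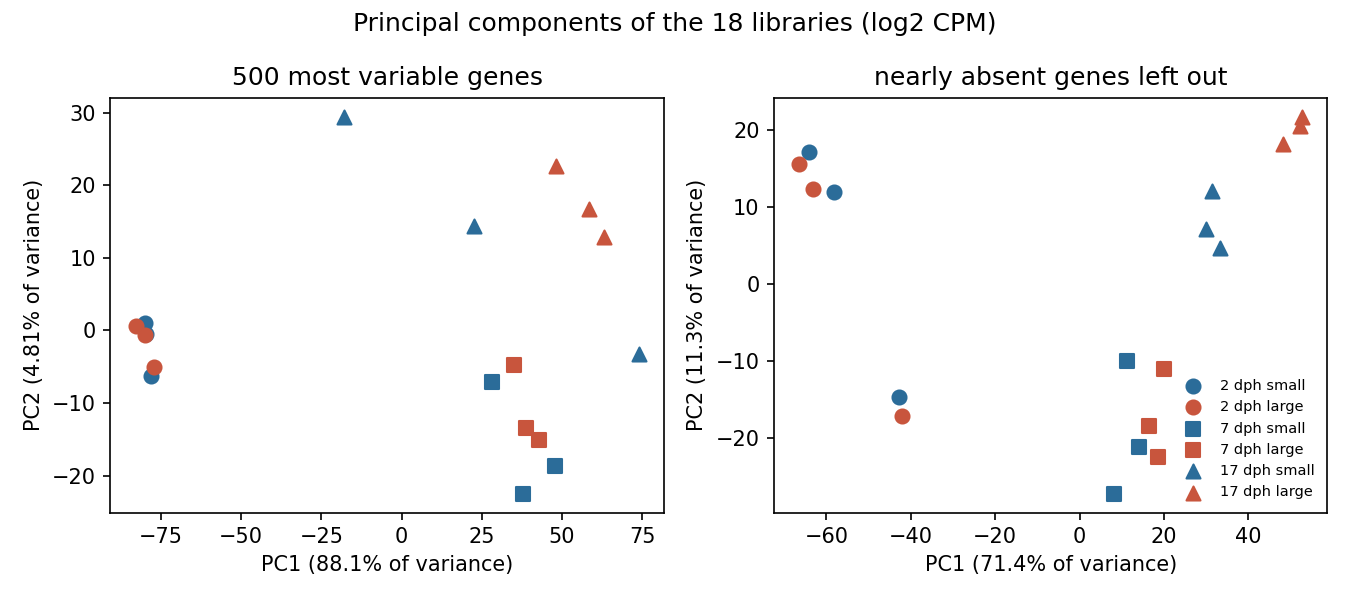
First and second principal components of log2 CPM for the 18 libraries, with all genes eligible (left) and without genes nearly absent at 2 dph (right); circles, squares and triangles stand for 2, 7 and 17 dph, and color for size class. On the right the 17 dph large libraries lie at 48.13 to 52.82 on the first component and the small ones at 29.88 to 33.28, while on the left 17 dph small replicate 3 lies at -17.96.

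From 2 to 7 dph, rises far outnumbered falls: 4837 genes rose and 537 fell (n = 3 spawns per age, edgeR quasi-likelihood test, adjusted p below 0.05). Gene c117765_g1 had 0 reads at 2 dph and 24 ± 12.1 CPM (SD, n = 3) at 7 dph, at least 468-fold higher against a limit of 3 reads over the 2 dph libraries (adjusted p = 0.00137, and 0.0884 in small larvae alone). Gene c121268_g1 rose from 1 read at 2 dph to 28.9 ± 5.34 CPM, a ratio of 2210 with a 95% counting interval of 303 to 66700. The steepest falls were those of c114664_g1, from 538 ± 178 to 1.11 ± 0.29 CPM (log2 change -8.91, SE 0.396, adjusted p = 1.68e-06), and c115782_g1, from 275 ± 84.6 to 0.668 ± 0.139 CPM (log2 change -8.67, SE 0.371). Fold changes against so few reads depend on counting error.

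Much of this rise lay in a set of genes with almost no reads at 2 dph. The 3064 genes nearly absent at 2 dph included 2732 of the 4837 genes that rose, or 56.5%, and both named rising genes belong to them. Because the set was chosen for few reads at 2 dph and at least 100 reads over all libraries, that its members rise is largely fixed by the choice. They took 0.00183% to 0.00367% of a library's reads at 2 dph and 0.446% to 0.913% at 7 dph. Without this set the test called 1344 rises and 317 falls, and without 2 dph replicate 1 or replicate 2 the full test called 2318 and 3573 genes. Large larvae alone gave 5115 genes and small larvae alone 630.

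**Figure D2:**
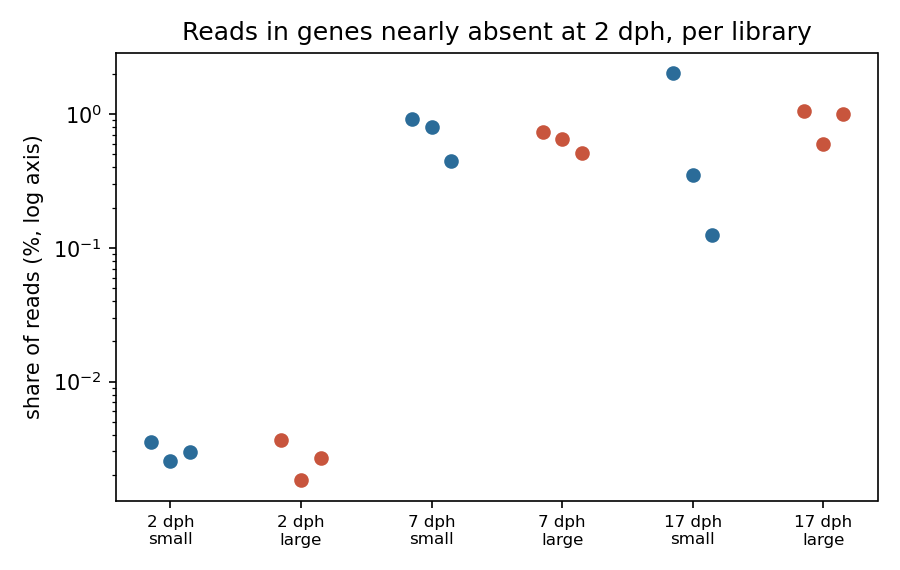
Share of each library's reads, in percent on a log axis, in the 3064 genes nearly absent at 2 dph; each point is a library, colored by size class. The shares are 0.00183% to 0.00367% at 2 dph by construction of the set, 0.446% to 0.913% at 7 dph, and 0.124% to 2.02% in 17 dph small larvae.

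From 7 to 17 dph, 348 genes rose and 106 fell, and from 2 to 17 dph 7751 rose and 2471 fell. Gene c192611_g1 rose from 0.0382 ± 0.0331 CPM (4 reads) at 7 dph to 20.6 ± 12.3 CPM at 17 dph, and c130626_g1 from 0.0836 ± 0.145 CPM (9 reads) to 30.5 ± 35.8 CPM (n = 3 spawns). The log2 change of c130626_g1 was 8.32 (SE 1.11), and 12.58 without 7 dph replicate 3. Both were almost unread in small larvae at 17 dph, at 0.284 ± 0.439 and 1.22 ± 1.11 CPM. Gene c114355_g1 fell by 2.34 (SE 0.403, adjusted p = 0.0285) and c113682_g1 fell by 2.15 (SE 0.338, adjusted p = 0.0179) on the log2 scale. Both calls were lost without 7 dph replicates 1 or 2, without 17 dph replicates 1 or 3, and in small larvae alone, with adjusted p of 0.0662 to 0.765. From 2 to 17 dph, c117485_g2 and c117765_g1 were at least 659-fold and 569-fold higher, against 0 reads at 2 dph, and c114664_g1 fell by 10.34 (SE 0.431) and c117856_g1 fell by 9.84 (SE 1.12) on the log2 scale. The nearly absent genes were 75 of the 348 and 2951 of the 7751 rises, and 6689 genes were called from 2 to 17 dph without them. With library totals in place of TMM, the 2 to 17 dph calls split into 6669 rises and 5089 falls, and those from 7 to 17 dph into 283 and 144.

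The interval from 7 to 17 dph was sensitive to the samples used. Leaving out a spawn also changes the mix of size classes, since the sums weight them by depth. With spawns of a common hatch day, as read from the codes, taken as a block, 1538 genes were called, 1022 rising and 516 falling. Large larvae alone gave 2357 genes and small larvae alone 16, and leaving out 7 dph replicates 1, 2 and 3 or 17 dph replicates 2 and 3 gave 139, 146, 823, 244 and 173 genes. Genes changed in both intervals mostly kept their direction: 131 rose in both and 32 fell in both, while 14 rose and then fell and 2 fell and then rose. Independent lists would share 21, 0.709, 6.38 and 2.33 genes. Groups simulated without change gave 0 calls in either interval, so they give no value for the overlap. Both intervals share the 3 spawns at 7 dph, which are too few to be divided, and part of the excess of genes that rose and then fell may come from them.

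Few or no genes passed the threshold between large and small larvae at 2 and 7 dph. At both ages edgeR called 0 of 68642 genes, with 7490 and 3174 genes at an unadjusted p below 0.05, and DESeq2 called 0 and 1. With siblings paired as a block, 0 genes were called at 2 dph and 54 at 7 dph, 20 higher and 34 lower in large larvae. Without 2 dph small replicate 3, edgeR called 3220 genes at 2 dph, 2615 of them higher in large larvae. Without 7 dph small replicate 1 it called 2.

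By 17 dph, 1528 genes were higher and 715 lower in large larvae (n = 3 per group, edgeR quasi-likelihood test, adjusted p below 0.05). The fitted difference was at least 2-fold in 1080 and 536 of them. Gene c192611_g1 was at 43.5 ± 24.2 CPM in large and 0.284 ± 0.439 CPM in small larvae (log2 difference 7.24, SE 0.655, adjusted p = 3.01e-05). Gene c165033_g1 was at 41.6 ± 24.1 and 0.459 ± 0.59 CPM (log2 difference 6.51, SE 0.631, adjusted p = 0.000182). Both belong to the genes nearly absent at 2 dph. Genes c96540_g1 and c107956_g1 were lower in large larvae, at 3.21 ± 0.803 against 51.1 ± 31.9 CPM (log2 difference -4.01, SE 0.814, adjusted p = 0.0113) and at 2.28 ± 0.702 against 36.2 ± 13.8 CPM (log2 difference -3.95, SE 0.604, adjusted p = 0.00149). The call of c96540_g1 was lost without 17 dph large replicate 1 (adjusted p = 0.053) or replicate 2 (adjusted p = 0.0698).

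Among the called genes, 1528 of 1528 higher and 713 of 715 lower genes had the same direction in all 3 sibling pairs, and large and small larvae did not overlap in 1526 and 711. The same libraries chose these genes, so such agreement is largely fixed by the calls. Over all tested genes the groups did not overlap in 31.8%, where chance gives 10%. The 2 called genes whose pairs disagreed had 20450 and 18689 reads in 17 dph small replicate 1 and at most 34 and 41 in any other library, so their calls (log2 differences -9.14 and -8.83) rest on that library alone; they were singled out after their values were seen. Abundant genes leaned towards large larvae: of 117 genes with a mean above 1000 CPM at 17 dph, 25 were higher and 0 lower, of 1020 genes at 100 to 1000 CPM 184 were higher and 11 lower, and of 42201 genes at 1 to 10 CPM 489 were higher and 456 lower. The 1528 higher genes took 16.5 ± 2.02% of reads in large and 8.2 ± 0.451% in small larvae, a share measured on the libraries that chose them.

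**Figure D3:**
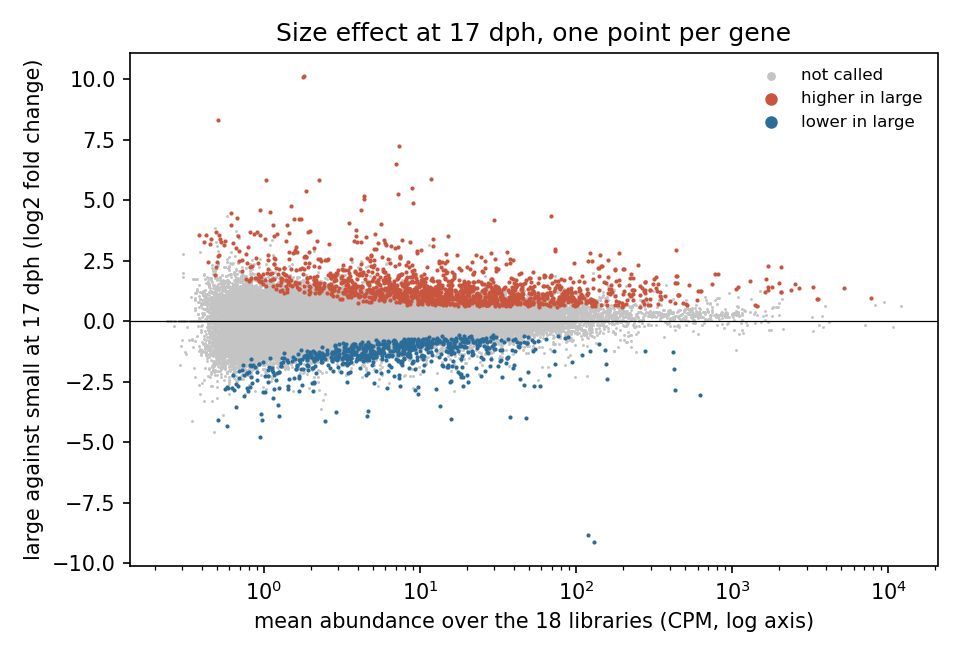
Log2 fold change of large against small larvae at 17 dph for each tested gene, against its mean CPM over the 18 libraries on a log axis; red and blue points passed an adjusted p below 0.05 (1528 higher and 715 lower genes). The lowest pair of points, at -9.14 and -8.83, rests on a single library.

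With siblings paired (replicate block), 9169 genes were called at 17 dph, 5773 higher and 3396 lower, including 2240 of the 2243. The directions are relative to the bulk of genes: scaling by library totals instead of TMM shifts all genes by -0.285 on the log2 scale and gives 806 higher and 3393 lower genes. Without large replicates 1, 2 or 3 the count was 1393, 513 or 1368, and without small replicates 2 or 3 it was 630 or 848.

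The genes called at 17 dph leaned the same way at 7 dph but not at 2 dph. Of the 1528 higher genes 88.15% were also higher in large larvae at 7 dph, where 47.07% of all tested genes were, and of the 715 lower genes 92.87% were lower. At 2 dph 22.19% of the higher genes were higher, where 42.93% of all tested genes were. Of the lower genes 36.92% were lower, to be set against the remaining tested genes. The median fitted differences were -0.238 and 0.139, so both sets leaned the opposite way. In 2 dph replicate 3 they did not, with medians of 0.0952 and -0.0203. The mean log2 difference over the higher genes minus that over the lower genes was taken in each pair. It was 0.826 ± 0.133 (SD, n = 3 pairs) at 7 dph and -0.35 ± 0.446 at 2 dph. The difference between the ages was 1.18 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 pairs allow). The libraries at 2 and 7 dph share the fit but not the values that chose the genes.

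**Figure D4:**
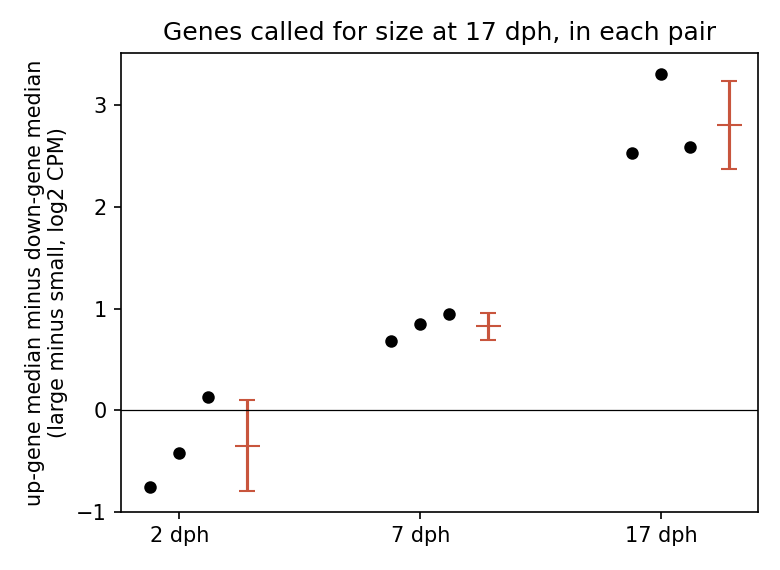
Mean large minus small log2 CPM over the 1528 genes higher at 17 dph minus that over the 715 lower genes. Black points are sibling pairs, and red marks the mean and SD per age (n = 3 pairs). The axis label names medians, but the plotted values are means over genes. The 7 dph pairs lie at 0.681 to 0.944 and the 2 dph pairs at -0.753 to 0.129; the 17 dph values come from the libraries that chose the genes.

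The size effect differed between 17 and 2 dph in 1322 genes, 846 with a more positive and 476 with a more negative effect at 17 dph (edgeR interaction test, adjusted p below 0.05). Gene c70852_g1 rose to 161 ± 60.2 CPM in large and 9.01 ± 2.7 CPM in small larvae at 17 dph, against 0.216 ± 0.208 and 0.501 ± 0.325 CPM at 2 dph (difference of log2 effects 5.05, SE 1.01, adjusted p = 0.0255). Gene c39962_g1 was at 40.6 ± 12.8 against 1.07 ± 0.305 CPM at 17 dph (difference 6.08, SE 1.23, adjusted p = 0.0261). Its difference rests on 10 reads in all at 2 dph, and was 9.80 without 2 dph large replicate 1 and 4.71 without 2 dph small replicate 2. In the other direction, c118004_g1 was at 36.3 ± 3.29 CPM in large and 17.5 ± 9.39 CPM in small larvae at 2 dph, and at 2.03 ± 1.27 against 12.9 ± 5.8 CPM at 17 dph (difference -3.52, SE 0.594, adjusted p = 0.0141). Gene c102769_g1 gave a difference of -3.36 (SE 0.642, adjusted p = 0.0208). The blocked fit called 11106 genes, 6099 and 5007, including all 1322. With library totals the split was 474 and 4671, after a shift of -0.427 on the log2 scale, and the count moved with most libraries. Without 2 dph large replicates 1 or 2 it was 100 or 73, without 2 dph small replicates 1, 2 or 3 it was 161, 176 or 10400 (4251 more positive and 6149 more negative, a turned majority), without 17 dph large replicates 2 or 3 it was 62 or 638, and without 17 dph small replicates 1, 2 or 3 it was 272, 111 or 282. Without 2 dph large replicates 1 or 2, 2 dph small replicates 1 or 2, or 17 dph large or small replicate 2, calls of c39962_g1, c70852_g1 or c102769_g1 were lost (adjusted p of 0.051 to 0.168), while that of c118004_g1 was kept. Thinning all libraries to the shallowest also ended the calls of c39962_g1 (adjusted p = 0.103, and 0.0631 with the block) and c70852_g1 (adjusted p = 0.0557).

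The size effect differed between 17 and 7 dph, and between 7 and 2 dph, in 0 genes by edgeR, with 3652 and 2743 genes at an unadjusted p below 0.05. DESeq2 called 76 and 1, and the blocked fit 52 and 0. Without 17 dph large replicates 1 or 3, edgeR called 8 and 1 genes for the difference between 17 and 7 dph. Over all ages together 216 genes differed by size, 132 higher and 84 lower in large larvae, and the blocked fit called 4523, 2293 and 2230, including all 216. Gene c42739_g1 was higher in large larvae in all 9 pairs (mean log2 difference 1.48, SE 0.255, adjusted p = 0.0195), reaching 130 ± 40.5 against 22.3 ± 7.77 CPM at 17 dph, and so was c68335_g2 (1.44, SE 0.218, adjusted p = 0.00954), by 0.0859 in 2 dph replicate 3 and by 3.43 in 17 dph replicate 2. The naming rule asks for the same direction in all pairs, so this agreement is fixed by the choice. Of the 216 genes, only 29 higher and 23 lower ones met that rule and the mean of 10 CPM. Genes c107956_g1 (-2.20, SE 0.314, adjusted p = 0.00588) and c110213_g1 (-2.04, SE 0.323, adjusted p = 0.0118) were lower on average. In 2 dph replicate 1 they hardly differed (-0.000671 and -0.116), and the largest differences, -2.75 to -4.36, were at 17 dph. With library totals the 217 calls split into 107 and 110, and without a low-count filter 1328 calls split into 481 higher and 847 lower, so the majority direction depends on these settings. It also turned with the block on thinned libraries (1452 and 1487). Without 17 dph replicates 1, 2 or 3 the count was 45, 9 (4 higher and 5 lower) or 67, without 7 dph replicates 2 or 3 it was 10 (4 higher and 6 lower) or 94, and without 2 dph replicates 2 or 3 it was 32 or 138. Calls of 1 or more of these genes were lost without replicate 2 of any age, 2 dph replicate 3 or 17 dph replicate 1 (adjusted p of 0.0538 to 0.14).

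Genes that were higher in large larvae at 17 dph overlapped with genes that rose between 2 and 7 dph, a comparison with no library on both sides. The lists shared 288 genes where independent lists would share 92 (odds ratio 3.82, Fisher's exact test, Benjamini-Hochberg adjusted p = 1.5e-67 over 4 tests). Genes lower in large larvae and genes that fell with age shared 31 against 5.39 (odds ratio 6.28, adjusted p = 2.18e-14). Lower genes that rose with age numbered 19 against 43.1 (odds ratio 0.423, adjusted p = 4.73e-05), and higher genes that fell with age 13 against 11.5 (adjusted p = 0.652). Genes are not independent replicates, so these p-values overstate the evidence. Without the genes nearly absent at 2 dph the first overlap was 267 against 38.1 (odds ratio 9.71), and the shortage of lower genes that rose with age was lost, at 19 against 18.4 (odds ratio 1.03).

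The developmental index, positive where large larvae lie on the later side of the age axis, averaged 0.0495 ± 0.142 over the 9 pairs (exact two-sided sign-flip permutation p = 0.312). At 17 dph the pairs gave -0.102, 0.112 and 0.398, and without the last of them, replicate 3, the mean over all ages was 0.00596. The difference between size classes along the age axis was thus within the spread between pairs. Restricting the axis to genes of at least 10 CPM gave 0.0618 (exact p = 0.0469), and leaving out the genes nearly absent at 2 dph, a choice made after the data were seen, gave 0.0721 ± 0.0665 (exact p = 0.0156). In that setting the pairs gave 0.0833, 0.179 and 0.164 at 17 dph and 0.0464, 0.0933 and 0.0653 at 7 dph. At 2 dph they gave -0.00424, -0.00857 and 0.0302.

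Over all ages together, library composition differed between the size classes by less than the spread between pairs. The 100 most abundant genes took 0.664 ± 3.17 percentage points more of the reads in large than in small larvae (n = 9 pairs, exact sign-flip permutation p = 0.57, adjusted p = 0.715 over 2 measures). This mean was 1.43 without 2 dph replicate 2, and 0.281, 0.104 or 0.328 without 17 dph replicates 1, 2 or 3. At 17 dph alone they took 25.17% in large and 21.09% in small larvae, a difference of 4.08 ± 0.945 points seen in 3 of 3 pairs (exact p = 0.25, the smallest that 3 pairs allow). The difference was -2.047 ± 3.09 points at 2 dph and -0.04 ± 0.615 at 7 dph, so the mean over ages joins opposite signs. The number of genes detected at equal depth differed by -852.7 ± 8900 (exact p = 0.715), and the sign of this mean changed without 17 dph replicate 1 (873.6) or replicate 2 (666.2). Between 2 and 7 dph the number detected went from 102500 ± 4350 to 111900 ± 4250 (n = 3 spawns, exact permutation p = 0.1, the smallest possible, adjusted p = 0.15 over 6 tests).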

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

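The tests of depth, of the nearly absent genes and of the index without them were chosen only after the results were seen, and so were the divisions that exchange siblings; the bounds for the other divisions of the libraries were also written after. These results stood out because an effect of size differed between ages. The number of genes whose size effect differed between 17 and 2 dph was 1322 by the interaction test. The named genes among them differed by 6.08 (c39962_g1), 5.05 (c70852_g1), -3.52 (c118004_g1) and -3.36 (c102769_g1) on the log2 scale. Large larvae had more genes detected at equal depth than their siblings in 3 of 3 pairs at 2 dph, with a mean difference of 7361. At 7 dph they had fewer in 3 of 3 pairs, with a mean difference of -1431, and at 17 dph more in 1 of 3, with a mean difference of -8488 ± 9300. This contrast between ages was not tested.

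The size effect at 17 dph was weighed against technical explanations. Thinning all libraries to the shallowest gave 1440 of 48123 tested genes, with 35 in the highest other division of the 6 libraries under that fit. Leaving out the genes nearly absent at 2 dph gave 2431 of 65974, with 3 in the highest other, so neither unequal depth nor those genes account for the size effect as a whole. A candidate explanation is that large larvae are further along the course of development. The index chosen before the data were examined gave an exact p of 0.312, and of 7 other settings 3 fell below 0.05, among them the index without the nearly absent genes (exact p = 0.0156), so this remains a hypothesis.

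Other divisions of the libraries bear on chance. At 2, 7 and 17 dph, 3 against 3 libraries make only 10 divisions, too few for a share below 0.05. The real division at 17 dph gave 2243 genes, with 1 of 10 as large and 48 in the highest other, and the 3 other divisions that part all siblings gave 0. At 2 and 7 dph the real counts were 0, so 10 of 10 were as large, with 500 and 1 in the highest other. For the age changes the real counts were 5374, 454 and 10222, with 1 of 10 as large and 0 in the highest other for each. Of 100 divisions drawn within ages, 3 gave as many as the 1322 genes of the 17 against 2 dph difference (highest other 4889), a share below 0.05. Most of these divisions put siblings together, however, and among the 32 that only exchange siblings at 2 and 17 dph, 2 were as large, a share of 0.0625, so chance cannot be excluded for this count. The larger of them, with 1808 genes, exchanged the siblings of 2 dph replicate 3. All 7 other divisions with calls left the 17 dph pairs as they were. They keep the size effect at 17 dph whole, so they do not show what chance alone would give. With the replicate block the real division gave 11106 genes, 1 of 32 as large, and that exchange gave 9630. For the size effect over all ages, 4 of 100 gave as many as 216 genes (highest other 877), which is borderline: of the first 80 draws of the same series 4 were as large, a share of 0.05, which would not exclude chance. Of 100 divisions that only exchange siblings, 2 were as large, the real one included (highest other 889). The division with 889 exchanged all 3 pairs at 7 and at 17 dph and 0 at 2 dph. It kept the size effects of 7 and 17 dph whole and turned them only against 2 dph, so it does not show what chance alone would give. With the replicate block, 8 of 60 such divisions gave as many as the 52 genes of the 17 against 7 dph difference (highest other 9222), so chance cannot be excluded for them. The others as large had exchanged the 17 dph siblings in none or in all 3 pairs, so they kept that size effect whole. The size effect differences between 7 and 2 dph and between 17 and 7 dph were 0, so 100 of 100 were as large, with 1550 and 7965 genes in the highest others. Among the 100 divisions that only exchange siblings, 13 others called genes for the 17 against 7 dph difference, up to 1877. In each of these, the siblings of 17 dph had been exchanged in none or in all 3 pairs, so the size effect at 17 dph was left whole. The source of the higher counts in divisions that put siblings together was not shown.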

How the results depend on the processing

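Alternatives that left out the genes nearly absent at 2 dph, scaled by library totals, thinned the libraries or combined these with a block were chosen after the data were seen. Over all alternatives, the named genes kept their direction in 471 of 471 values, and in 47 of them they no longer passed the threshold. These genes were chosen on the same libraries for the largest changes with agreeing pairs or no overlap. Their kept direction is therefore largely fixed by the choice. For 7 to 17 dph, c192611_g1 and c130626_g1 have no value with 18 separate libraries, in small larvae alone or with at least 10 CPM in 3 sums, and DESeq2 gave c130626_g1 no adjusted p. Settings without the nearly absent genes have no value for named genes of that set. RLE size factors and at least 1 CPM in 3 libraries moved no count of size calls by over 1.5 times. For the changes below the cause was not tested unless the setting removes genes or samples.

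The replicate block gave 54 (7 dph), 9169 (17 dph), 4523 (all ages), 52 (17 against 7 dph) and 11106 genes (17 against 2 dph), and changed no other size call. Spawns of a replicate number correlated across ages at 0.119 on average, and the numbers as a block gave 689 genes for 7 to 17 dph. Without a low-count filter the counts were 35 (2 dph), 87 (7 dph), 1328 (all ages, 481 higher and 847 lower in large larvae), 9 (7 against 2 dph), 154 (17 against 7 dph), 9239 (2 to 7 dph) and 1565 (7 to 17 dph). At least 10 CPM in 3 libraries gave 341 genes over all ages, and in 3 sums 978, 112 and 2469 for 2 to 7, 7 to 17 and 2 to 17 dph; at least 1 CPM in 3 sums gave 3499 for 2 to 7 dph. Tests against a fold change gave 407 (17 dph, 1.5-fold) and 3132, 94 and 5054 (ages, 2-fold). DESeq2 gave 1 (7 dph), 794 (all ages), 1 (7 against 2 dph), 76 (17 against 7 dph), 2916 (17 against 2 dph) and 1185 (7 to 17 dph).

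Libraries of 17 dph only gave 3969 genes. For ages, 18 separate libraries gave 1140 (7 to 17 dph), large larvae only 2357 (7 to 17 dph) and 16246 (2 to 17 dph), small larvae only 630, 16 and 3557, and the hatch-day block 1538 (7 to 17 dph). Without the nearly absent genes the counts were 5 (17 against 7 dph), 1661 (2 to 7 dph) and 6689 (2 to 17 dph), and with the replicate block as well 325 (7 dph), 11098 (17 dph), 6161 (all ages), 3, 330 and 14082 (differences 7 against 2, 17 against 7 and 17 against 2 dph). Library totals gave 4199 (17 dph) and 5145 (17 against 2 dph). Thinned libraries gave 1440 and 826 for these, and with the replicate block 1, 121, 5176 and 2939 (2, 7, 17 dph and all ages) and 1, 86 and 5596 (the differences). The blocked count at 17 dph was 7821, 2422 or 5145 without replicate 1, 2 or 3.

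With each replicate left out in turn, counts ran from 0 to 3220 (2 dph), 0 to 2 (7 dph), 513 to 2662 (17 dph), 9 to 218 (all ages), 0 to 8 (17 against 7 dph), 62 to 10400 (17 against 2 dph), 2318 to 7494 (2 to 7 dph) and 139 to 823 (7 to 17 dph). The developmental index was 0.0618 with genes of at least 10 CPM, 0.0721 without the nearly absent genes and 0.169 as a Spearman correlation without them, each now past the threshold. The difference in genes detected ran from -2558 to 873.6. At a depth of 3706225 reads in each library, 48123 genes could be tested and 1440 were called at 17 dph.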

Other observations

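All tests in this part were chosen after the patterns were seen. Among the 346 genes nearly absent at 2 dph with at least 5 CPM, a single factor per library held 86.5% (median over genes) of the variance among the 7 and 17 dph libraries, against 13.2% in genes matched on abundance and 7.5% in the other genes that rose from 2 to 7 dph. The factor spanned 2.29-fold between the 7 dph libraries and 35.8-fold between the 17 dph libraries, but 6.98-fold without 17 dph small replicate 3 and 18.6-fold without small replicate 1. The share of all 3064 nearly absent genes in small larvae at 17 dph was 16.3 times higher in replicate 1 than in replicate 3, with depths that differed by 1.23 times, so depth does not account for it. The median shift of the other genes that rose from 2 to 7 dph spanned only 1.14-fold between the 17 dph libraries. Rising genes outside the set rose less, however, by a median log2 change of 1.84 against 6.647 over all rising genes. The same difference in developmental state would move them less, so this span does not exclude such a difference. A candidate source is RNA of another organism, such as food in the gut, which would rise and fall as a unit; a larval gene program that acts as a unit, for example in a single tissue, would look the same and was not tested, and no sequence was examined.

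Spawns that the collection codes, read as month and day, assign to a common hatch day deviated from their age means in a similar way. The 6 pairs of such spawns at different ages correlated at 0.282 on average over 77337 genes, against -0.084 for the 21 other pairs (exact one-sided permutation p = 0.0185 over 216 assignments). With counts thinned to a common depth the mean was 0.195 (exact p = 0.00926, the smallest the assignments allow), so unequal depth does not account for it. Parents or rearing conditions that such spawns share may contribute, and a library batch that follows the same dates cannot be told apart from them because the labels give none.

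Of all genes with at least 100 reads, 2 had at least 90% of their CPM in a single library, and both were in 17 dph small replicate 1, where they took 0.433% of the reads. In the 17 other libraries they had between 4 and 41 reads each. Their cause was not tested.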
